A study of Mus musculus with 21 samples.

How the data were processed

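RNA sequencing libraries were made from mouse thyroid tissue as stranded poly(A) libraries, per the labels' protocols. The submitters' processing notes name FastQC 0.11.7, Trimmomatic 0.38, HISAT2 2.1.0, StringTie 2.1.3b and the mm10 genome build, with no role or order. The gene annotation, the use of strand and the step that made whole-number counts are not given in the sources used here. The deposited tables hold 1 read count and 1 FPKM value per gene and library, per the file headers, for 45777 genes, with 1 table per week. The deposited TPM values were not used. Libraries were taken from the labels into 7 groups of 3, and no library was left out or counted as a duplicate: the 21 pairs of libraries within groups had a chi-square per degree of freedom of 11.7 to 161 over genes, above the 1 of sampling noise. Because genes with near-identical copies and overlapping genes, such as those of the Gnas locus, can share reads, their values are uncertain.

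Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes passed filterByExpr, libraries were scaled by TMM (factors 0.972 to 1.05 at 1 week and 0.935 to 1.1 at 4 weeks), and dispersions were estimated robustly. A quasi-likelihood F test was made for each contrast of group means, with Benjamini-Hochberg adjustment and a threshold of 0.05. The 9 libraries of 1 week were fitted together (16956 genes), as were the 12 of 4 weeks (17355 genes) and all 21 for differences between times (17715 genes). Groups shared 1 estimate of the spread (biological coefficient of variation 0.185, 0.184 and 0.189). CPM values are TMM-normalised counts within each week. The marker scores are means of log2 CPM with a prior count of 2. Of 754 symbols in 46 gene lists 734 were in the tables, and 45 lists with at least 3 tested members were tested with limma's camera (limma 3.58.1) with a preset correlation of 0.01 and again with an estimated correlation. The tests of the comparisons, the lists, contrasts and the rule for named genes were fixed before the data were examined. Of the alternatives 3 were added later: the skeletal muscle score as a covariate, the removal of both libraries with thymocyte transcripts, and the removal of Tg, mitochondrial and ribosomal RNA genes before scaling. Tests of explanations other than the splits of libraries were chosen later, those of dilution after their results were seen.

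Named genes were, first, Tshb, Cga and the tested members of the thyroid lists, second, the 6 highest and 6 lowest log2 fold changes among called genes with a mean CPM of at least 5 and no overlap between the groups' libraries (this last not for differences of effects), and last, up to 4 members of each described list with the smallest p. Predicted genes and immunoglobulin and T cell receptor genes were not taken by the second part, and genes with 0 counts throughout a group are not given a fold. For space, fewer genes of each part are given, taken in order of size or p, and in the comparisons of TSH-MMI with Empty only the thyroid genes with the smallest p beside Slc26a4, Slc5a5, Tshr and Tg, and fewer lists are described. This was done after the values were seen. Some genes of the thyroid lists are not reported here.

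Alternatives were DESeq2 1.42.0, limma's trend method on log2(FPKM + 1), size factors by relative log expression (RLE), no filter on low counts, only the compared groups, the replicate number as a block, and leaving out each library. Of 168 calls of named genes, counted per comparison, 119 kept an adjusted p under 0.05 at each setting that gave one and 49, listed as ended, did not. In data simulated for TSH against Empty at 1 week, edgeR recovered 55.2%, 77.6% and 97% of genes changed 1.5-, 2- and 4-fold, with 7.27% of calls false, against 18.5% for DESeq2. Positions are from the GENCODE annotation of GRCm38, matched by gene identifier.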

Results

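The series holds RNA sequencing of thyroid tissue from C57BL/6J mice given a pLIVE plasmid, a vector made for expression in the liver, either empty or carrying the hormone TSH (thyrotropin), which drives thyroid growth and hormone synthesis through its receptor on thyroid follicular cells. Some animals also received methimazole (MMI), a drug that blocks the synthesis of thyroid hormone. There were 7 groups of 3 libraries. At 1 week these were the empty vector (Empty), the TSH vector (TSH) and the TSH vector with methimazole (TSH-MMI). At 4 weeks the same 3 groups were joined by the empty vector with methimazole (Empty-MMI). Totals ran from 32244842 to 51886245 counts per library over 21 libraries and 45777 genes. The labels do not state that each library came from a separate animal, so the p-values measure the spread between these samples. Values rest on n = 3 libraries per group, and log2FC stands for the fitted log2 fold change, given with its standard error (SE).

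Tshb and Cga, which encode the subunits of TSH, had 0 counts in each of the 21 libraries, which allows up to 3 counts per library. Thyroglobulin (Tg, chromosome 15, 66670753 to 66850721, gene identifier 21819, on GRCm38), the protein on which thyroid hormone is built, took 24.5% ± 1.75 of all counts in Empty at 1 week (mean ± SD, n = 3), 20.4% ± 2.29 in TSH and 18.3% ± 0.923 in TSH-MMI. At 4 weeks its share was 21.9% ± 4.46 in Empty, 24.1% ± 3.14 in Empty-MMI, 29.5% ± 1.26 in TSH and 21.1% ± 3.43 in TSH-MMI.

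Transcripts of neighbouring tissues differed between libraries. The mean log2 CPM of the skeletal muscle markers was 8.05, 7.21 and 8.01 in the Empty libraries of 4 weeks, against 1.83, 3.65 and 1.15 in Empty-MMI, -1.46, 5.58 and 4.96 in TSH and -1.57, 1.84 and 4.27 in TSH-MMI. At 1 week it was -0.27, 5.11 and 5.89 in Empty, 4.95, 2.86 and 7.28 in TSH and 4.78, 2.16 and 1.97 in TSH-MMI. The parathyroid marker score was 1.17 in Empty replicate 3 and -1.74 in TSH replicate 1 at 4 weeks. Immature thymocyte markers reached 3.92 in Empty replicate 3 and 1.27 in TSH-MMI replicate 2 at 1 week, and lay below 0 in the other libraries.

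**Figure D1:**
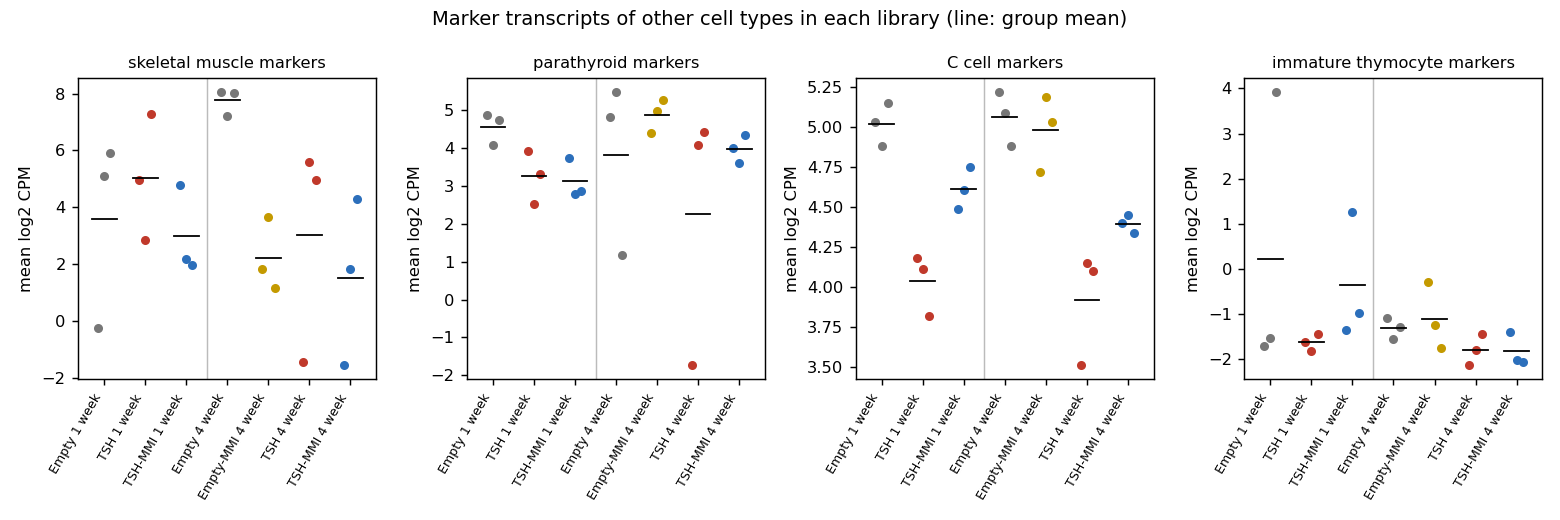
Mean log2 CPM of the markers of skeletal muscle, parathyroid, C cells and immature thymocytes in each library (points, 3 per group) with the group mean (line), by group. The muscle score of the 3 Empty libraries at 4 weeks lies between 7.21 and 8.05, above every other library but TSH replicate 3 of 1 week at 7.28.

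The first comparison asked what the TSH vector changed in the thyroid after 1 week. Slc26a4, which encodes pendrin, the anion exchanger of the apical follicular membrane, rose 16.7-fold in TSH over Empty (log2FC 4.06, SE 0.28, edgeR adjusted p = 4.19e-06), to 5.08 ± 0.726 against 0.299 ± 0.0799 normalised CPM (mean ± SD, n = 3). Tshr, the TSH receptor, rose 2.49-fold (log2FC 1.32, SE 0.09, edgeR adjusted p = 4.24e-06), and Slc5a5, the sodium iodide symporter, rose 1.83-fold (log2FC 0.87, SE 0.12, edgeR adjusted p = 0.000369). By edgeR 29 of 30 mitosis genes, 15 of 21 matrix markers and 15 of 16 macrophage markers rose, and 11 of 13 C cell markers fell. In all, it called 2510 higher and 1584 lower among 16956 genes tested. 18S ribosomal RNA took 1.55% ± 0.125 of counts in Empty, 0.942% ± 0.306 in TSH and 0.963% ± 0.202 in TSH-MMI (mean ± SD, n = 3), and more in each Empty library than in each of the others.

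Of the thyroid hormone synthesis genes 9 of 17 rose and 2 fell, or 11 and 3 adjusted over the list alone (median log2FC 0.48, camera adjusted p = 0.000652, adjusted p = 0.186 with an estimated correlation). Slc26a7, an anion exchanger needed for iodide organification, rose (log2FC 0.51, SE 0.07, edgeR adjusted p = 0.000378). Dio2 and Dio1, the deiodinases that turn thyroxine into the active hormone, rose (log2FC 1.82 and 0.48, SE 0.27 and 0.09, edgeR adjusted p = 0.00122 and 0.00254), as did Ano1, a calcium-gated anion channel, Duox1, a peroxide-producing oxidase, and Kcnq1, a potassium channel (log2FC 0.79, 0.80 and 0.43, SE 0.14, 0.22 and 0.13, edgeR adjusted p = 0.00277, 0.0184 and 0.0344). Slc16a10, a transporter of thyroid hormone, fell (log2FC -0.64, SE 0.12, edgeR adjusted p = 0.00269), and Tg stood at log2FC -0.26, SE 0.10, edgeR adjusted p = 0.0652. Among the TSH receptor and thyroid transcription factors 3 of 9 rose and 2 fell, or 3 and 4 adjusted over the list alone (median log2FC -0.07, camera adjusted p = 0.69, adjusted p = 0.879 with an estimated correlation). Beside Tshr, Glis3 and Creb3l1 rose (log2FC 0.61 and 0.56, SE 0.16 and 0.15, edgeR adjusted p = 0.0233 and 0.0206), and Foxe1 and Gnas, which encodes the stimulatory G protein subunit, fell (log2FC -0.42 and -0.51, SE 0.12 and 0.13, edgeR adjusted p = 0.0291 and 0.0163). Foxe1, Gnas and Kcnq1 lost calls without the libraries with thymocyte transcripts, at log2FC -0.35, -0.48 and 0.33, SE 0.14, 0.15 and 0.14 (adjusted p = 0.104, 0.0574 and 0.116). Creb3l1, Duox1, Foxe1, Glis3, Gnas and Kcnq1 lost calls without Empty replicate 1 (adjusted p = 0.0818, 0.0803, 0.0955, 0.0613, 0.058 and 0.0936) and TSH replicate 3 (0.07, 0.058, 0.113, 0.0673, 0.0595 and 0.0604). Creb3l1, Duox1 and Glis3 lost calls without Empty replicate 2 (adjusted p = 0.0721, 0.0618 and 0.083). Foxe1 lost the call with the replicate block (adjusted p = 0.0605). Foxe1 and Gnas lost calls with limma on FPKM (adjusted p = 0.0777 and 0.101). Foxe1 and Kcnq1 lost calls with only the compared groups fitted (adjusted p = 0.0606 and 0.0734) and without Empty replicate 3 (0.0685 and 0.101). Foxe1 and Glis3 lost calls without TSH replicate 1 (adjusted p = 0.0908 and 0.0612). Glis3, Gnas and Kcnq1 lost calls without TSH replicate 2 (adjusted p = 0.0647, 0.0624 and 0.149).

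Of the mitosis genes 29 of 30 rose, or 30 adjusted over the list alone (median log2FC 2.74, camera adjusted p = 7.86e-48, adjusted p = 0.164 with an estimated correlation). Kif20a, a mitotic kinesin, Hmmr, a spindle protein, and Anln, which acts in cytokinesis, rose (log2FC 3.52, 3.63 and 3.16, SE 0.20, 0.23 and 0.19, edgeR adjusted p = 1.67e-06, 2.9e-06 and 2.9e-06). Of the genes of the G1/S step and DNA replication 11 of 30 rose, or 15 adjusted over the list alone (median log2FC 0.61, camera adjusted p = 5.24e-06, adjusted p = 0.627 with an estimated correlation). Ccne2, a cyclin, and Tk1, thymidine kinase, stood higher (log2FC 2.05 and 1.23, SE 0.24 and 0.19, edgeR adjusted p = 0.000138 and 0.000755). In the p53 and DNA damage list 9 of 20 rose and 2 fell, or 10 and 3 adjusted over the list alone (median log2FC 0.38, camera adjusted p = 0.00885, adjusted p = 0.194 with an estimated correlation). Ccng1 and the stress cytokine gene Gdf15 rose (log2FC 0.56 and 3.43, SE 0.08 and 0.39, edgeR adjusted p = 0.000556 and 0.00145). Among antioxidant genes 14 of 25 rose and 2 fell, or 14 and 3 adjusted over the list alone (median log2FC 0.54, camera adjusted p = 2.76e-06, adjusted p = 0.49 with an estimated correlation). Gclc and Gclm, which make glutathione, were higher (log2FC 0.85 and 1.20, SE 0.10 and 0.14, edgeR adjusted p = 0.000132 and 0.000286). In the lysosome and thyroglobulin proteolysis list 18 of 24 rose, or 19 adjusted over the list alone (median log2FC 0.43, camera adjusted p = 7.86e-12, adjusted p = 0.194 with an estimated correlation). The cathepsin genes Ctss and Ctsl were higher (log2FC 1.37 and 1.23, SE 0.10 and 0.11, edgeR adjusted p = 6.6e-06 and 3.29e-05). Of the cAMP response genes 7 of 20 rose and 1 fell, or 9 and 1 adjusted over the list alone (median log2FC 0.36, camera adjusted p = 0.0239, adjusted p = 0.49 with an estimated correlation). Pde7b and Fos rose (log2FC 0.86 and 1.13, SE 0.08 and 0.17, edgeR adjusted p = 3.89e-05 and 0.000822). DESeq2 called 7 immediate early genes like Fos.

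Of the extracellular matrix and fibroblast markers 15 of 21 rose, or 16 higher and 1 lower adjusted over the list alone (median log2FC 1.41, camera adjusted p = 1.58e-53, adjusted p = 0.00189 with an estimated correlation). Fbn1, fibrillin, Lox, which crosslinks collagen, and Col3a1 rose (log2FC 2.25, 2.56 and 2.17, SE 0.10, 0.11 and 0.10, edgeR adjusted p = 2.44e-07, 2.7e-07 and 2.98e-07). Of the macrophage markers 15 of 16 rose, or 15 higher and 1 lower adjusted over the list alone (median log2FC 1.13, camera adjusted p = 1.34e-25, adjusted p = 0.039 with an estimated correlation). C1qb, a complement gene, and Csf1r, the receptor of a macrophage growth factor, were higher (log2FC 1.17 and 1.24, SE 0.08 and 0.10, edgeR adjusted p = 2.9e-06 and 9.77e-06). Of the endothelial markers 13 of 16 rose and 1 fell, or 14 and 1 adjusted over the list alone (median log2FC 0.59, camera adjusted p = 1.36e-09, adjusted p = 0.194 with an estimated correlation). Eng and Cdh5 stood at log2FC 1.24 and 0.73, SE 0.10 and 0.09, edgeR adjusted p = 1.48e-05 and 0.000161. Of the markers of cartilage, a tissue next to the thyroid, 5 of 10 rose and 1 fell, or 6 and 1 adjusted over the list alone (median log2FC 1.12, camera adjusted p = 4.99e-05, adjusted p = 0.144 with an estimated correlation). Cnmd and Col9a3 stood at log2FC 2.46 and 1.44, SE 0.18 and 0.13, edgeR adjusted p = 1.22e-05 and 2.77e-05.

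Markers of C cells, the calcitonin-producing cells of the thyroid, went the other way: 1 of 13 rose and 11 fell, or 1 and 11 adjusted over the list alone (median log2FC -1.04, camera adjusted p = 1.27e-09, adjusted p = 0.194 with an estimated correlation). Pcsk1 and Pcsk2, which cleave prohormones, fell and the receptor gene Ret rose (log2FC -1.02, -1.22 and 0.48, SE 0.12, 0.15 and 0.07, edgeR adjusted p = 0.000217, 0.000609 and 0.000536). For the parathyroid markers edgeR called 0 of 4, against 2 at an unadjusted p under 0.05, 2 by DESeq2, 1 by limma, and 0 adjusted over the list alone (median log2FC -1.57, camera adjusted p = 0.0356, adjusted p = 0.627 with an estimated correlation). For the skeletal muscle markers edgeR called 0 of 19, against 0 at an unadjusted p under 0.05, 0 by DESeq2, 0 by limma, and 0 adjusted over the list alone (median log2FC 1.03, camera adjusted p = 0.548, adjusted p = 0.902 with an estimated correlation).

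The highest genes of the naming rule were Slc34a2, a sodium phosphate cotransporter, and Iqgap3, which acts in cell division (log2FC 5.62 and 3.93, SE 0.82 and 0.18, edgeR adjusted p = 0.00411 and 4.29e-07). The lowest were Ptgds, prostaglandin D synthase, and Inmt, a methyltransferase (log2FC -2.35 and -2.32, SE 0.19 and 0.30, edgeR adjusted p = 1.14e-05 and 0.00055). Without TSH replicate 3 edgeR called 1795 higher and 854 lower, limma called 2598 higher and 1239 lower, and 1017 of the 4094 called genes changed at least 2-fold. Slc26a4 lies on chromosome 12, 31519827 to 31559969, gene identifier 23985, Tshr on chromosome 12, 91384563 to 91549808, gene identifier 22095, and Slc5a5 on chromosome 8, 70882889 to 70892757, gene identifier 114479 (GRCm38). The log2FC was 6.32 for Slc34a2 without Empty replicate 3.

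**Figure D2:**
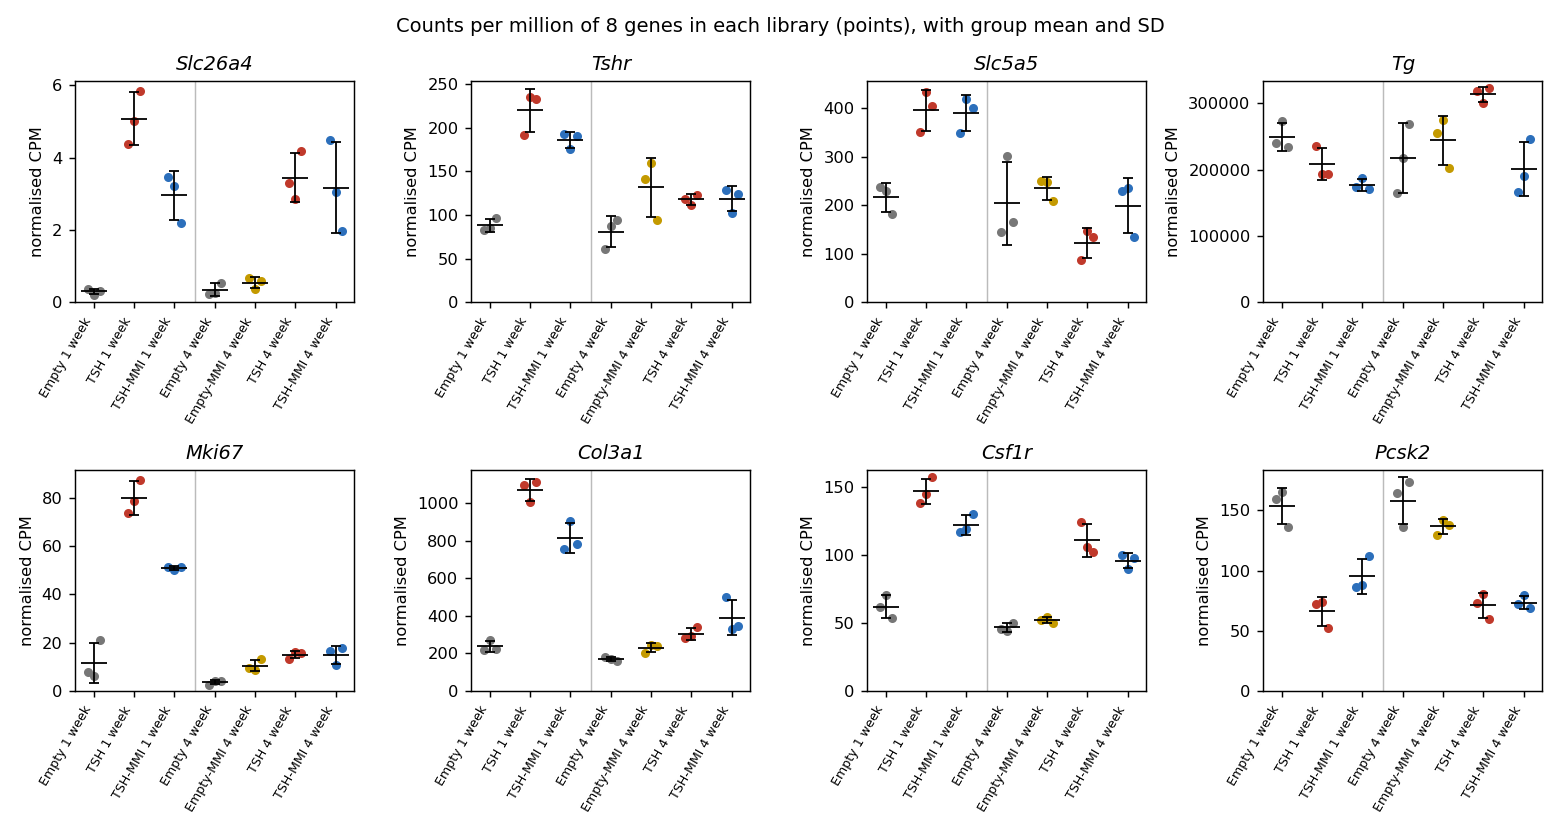
Normalised CPM of 8 genes (panels, chosen after their values were seen) in each library (points) with the group mean and SD (bars), by group; the vertical line parts 1 week from 4 weeks. Slc26a4, Csf1r and Col3a1 lie higher in each TSH library than in each Empty library of the same week, and Pcsk2 lies lower.

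Methimazole was added to TSH at 1 week to ask what the drug changed under TSH drive. Few genes passed: 3 fell, namely the collagen genes Col15a1 and Col6a1 and Tbc1d4, a regulator of glucose transporter traffic (log2FC -0.59, -0.56 and -0.51, SE 0.07, 0.07 and 0.06, edgeR adjusted p = 0.04, 0.0422 and 0.04). Slc26a4, Slc5a5, Tshr and Tg stood at log2FC -0.78, -0.02, -0.24 and -0.23, edgeR adjusted p = 0.356, 0.971, 0.472 and 0.526. By edgeR there were 0 higher and 3 lower, with 1462 genes at an unadjusted p under 0.05, DESeq2 called 36 higher and 112 lower and limma called 0. In simulated data for this comparison edgeR recovered 52.2%, 76.1% and 95.5% of genes changed 1.5-, 2- and 4-fold, and 9.15% of its calls were false. By edgeR 0 genes passed with the replicate block, with the muscle covariate, without TSH replicate 2 or 3, without TSH-MMI replicate 1, 2 or 3, and without both libraries with thymocyte transcripts. Col15a1, Col6a1 and Tbc1d4 lost calls with the muscle covariate, at log2FC -0.58, -0.56 and -0.51, SE 0.08, 0.08 and 0.07 (adjusted p = 0.129 for each). Col15a1, Col6a1 and Tbc1d4 lost calls without the libraries with thymocyte transcripts, at log2FC -0.57, -0.51 and -0.56, SE 0.08, 0.07 and 0.07 (adjusted p = 0.0966 for each). Col15a1, Col6a1 and Tbc1d4 lost calls with the replicate block (adjusted p = 0.0976 for each), with limma (0.0544, 0.0572 and 0.226), without TSH replicate 1 (0.0692, 0.107 and 0.0869) and 2 (0.109, 0.137 and 0.137). Col15a1, Col6a1 and Tbc1d4 lost calls without TSH replicate 3 (adjusted p = 0.268 for each), TSH-MMI replicate 1 (0.11, 0.11 and 0.114), 2 (0.143, 0.172 and 0.114) and 3 (0.327, 0.331 and 0.327). Tbc1d4 lost the call with only the compared groups fitted (adjusted p = 0.062).

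In the matrix list 1 of 21 fell, or 10 adjusted over the list alone (median log2FC -0.33, camera adjusted p = 5.94e-17, adjusted p = 0.0459 with an estimated correlation). Fbn1 stood at log2FC -0.55, edgeR adjusted p = 0.135. For the mitosis genes edgeR called 0 of 30, against 2 at an unadjusted p under 0.05, 0 by DESeq2, 0 by limma, and 0 adjusted over the list alone (median log2FC -0.48, camera adjusted p = 4.31e-09, adjusted p = 0.664 with an estimated correlation). Of the interferon response genes edgeR called 0 of 25, against 8 at an unadjusted p under 0.05, 1 by DESeq2, 0 by limma, and 5 lower adjusted over the list alone (median log2FC -0.36, camera adjusted p = 2.04e-09, adjusted p = 0.664 with an estimated correlation). Among the C cell markers edgeR called 0 of 13, against 8 at an unadjusted p under 0.05, 4 by DESeq2, 0 by limma, and 7 higher adjusted over the list alone (median log2FC 0.48, camera adjusted p = 5.42e-13, adjusted p = 0.365 with an estimated correlation). Pcsk1 and Calca, which encodes calcitonin, stood at log2FC 0.48 and 0.86, edgeR adjusted p = 0.314 and 0.332. In the thyroid hormone synthesis list edgeR called 0 of 17, against 8 at an unadjusted p under 0.05, 0 by DESeq2, 0 by limma, and 1 higher and 1 lower adjusted over the list alone (median log2FC 0.03, camera adjusted p = 0.953, adjusted p = 0.977 with an estimated correlation). The skeletal muscle markers had a median log2FC of -2.53 (camera adjusted p = 7.93e-06, adjusted p = 0.664 with an estimated correlation).

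Against Empty, the combined treatment at 1 week raised Slc26a4 9.73-fold (log2FC 3.28, SE 0.28, edgeR adjusted p = 2.87e-05) and Tshr 2.11-fold (log2FC 1.08, SE 0.09, edgeR adjusted p = 2.77e-05). Of the mitosis genes 27 of 30 rose, or 29 adjusted over the list alone (median log2FC 2.23, camera adjusted p = 7.69e-42, adjusted p = 0.144 with an estimated correlation). Kif20a and Hmmr stood at log2FC 3.13 and 3.29, SE 0.20 and 0.23, edgeR adjusted p = 5.83e-06 and 9.42e-06. In edgeR 2307 higher and 1351 lower passed. Of the thyroid hormone synthesis genes 10 of 17 rose and 2 fell, or 10 and 3 adjusted over the list alone (median log2FC 0.53, camera adjusted p = 0.000149, adjusted p = 0.144 with an estimated correlation). Dio1, Slc26a7 and Slc5a5 rose (log2FC 0.68, 0.53 and 0.85, SE 0.09, 0.07 and 0.12, edgeR adjusted p = 0.000426, 0.000456 and 0.000613), as did Duox1 and its maturation factor Duoxa1 (log2FC 1.41 and 1.22, SE 0.22 and 0.20, edgeR adjusted p = 0.00108 and 0.0016). Tg fell (log2FC -0.49, SE 0.10, edgeR adjusted p = 0.0041).

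Of the matrix markers 15 of 21 rose and 1 fell, or 15 and 1 adjusted over the list alone (median log2FC 0.85, camera adjusted p = 7.53e-39, adjusted p = 0.00367 with an estimated correlation). Lox and Col3a1 stood higher (log2FC 2.50 and 1.77, SE 0.11 and 0.10, edgeR adjusted p = 4.56e-07 and 2.64e-06). Of the macrophage markers 15 of 16 rose, or 15 higher and 1 lower adjusted over the list alone (median log2FC 0.97, camera adjusted p = 4.01e-20, adjusted p = 0.0764 with an estimated correlation). C1qb and Cx3cr1 stood higher (log2FC 0.98 and 1.24, SE 0.08 and 0.10, edgeR adjusted p = 1.76e-05 and 1.82e-05). Among the C cell markers 1 of 13 rose and 5 fell, or 1 and 9 adjusted over the list alone (median log2FC -0.53, camera adjusted p = 0.00176, adjusted p = 0.664 with an estimated correlation). Ret and Pcsk1 stood at log2FC 0.62 and -0.55, SE 0.07 and 0.12, edgeR adjusted p = 0.000174 and 0.01. The parathyroid markers had a median log2FC of -1.84 (camera adjusted p = 0.00842, adjusted p = 0.664 with an estimated correlation) and the muscle markers a median log2FC of -1.53 (camera adjusted p = 0.226). The highest genes were Dcpp3, whose reads are uncertain because near-identical copies exist, and Slc34a2 (log2FC 6.08 and 4.96, SE 0.56 and 0.81, edgeR adjusted p = 0.000251 and 0.00785), and the lowest Fam222a and Inmt (log2FC -2.14 and -2.05, SE 0.56 and 0.29, edgeR adjusted p = 0.0347 and 0.00138). On FPKM limma called 3262 higher and 739 lower. By edgeR there were 1632 higher and 726 lower without Empty replicate 1 and 1448 higher and 646 lower without TSH-MMI replicate 3. Fam222a lost the call without the libraries with thymocyte transcripts, at log2FC -1.95, SE 0.81 (adjusted p = 0.181). Fam222a lost the call with no filter (adjusted p = 0.0643), without Empty replicate 1 (0.0898), 3 (0.0773), TSH-MMI replicate 2 (0.105) and 3 (0.118). The log2FC was 6.83 for Dcpp3 without Empty replicate 2, 5.47 and 5.67 for Dcpp3 and Slc34a2 without Empty replicate 3 and 4.26 for Slc34a2 without TSH-MMI replicate 1.

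After 4 weeks of the TSH vector, Slc26a4 stood 9.89-fold above Empty (log2FC 3.31, SE 0.38, edgeR adjusted p = 0.000158), at 3.45 ± 0.688 against 0.352 ± 0.169 normalised CPM (mean ± SD, n = 3). Dio2 rose 3.05-fold (log2FC 1.61, SE 0.27, edgeR adjusted p = 0.00227) and Ano1 1.48-fold (log2FC 0.57, SE 0.11, edgeR adjusted p = 0.00495). By edgeR 23 of 30 mitosis genes, 14 of 16 macrophage markers, 19 of 25 interferon response genes and 13 of 21 matrix markers rose, and 11 of 13 C cell markers fell. It called 1478 higher and 974 lower among 17355 genes tested.

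Of the thyroid hormone synthesis genes 4 of 17 rose and 1 fell, or 6 and 1 adjusted over the list alone (median log2FC 0.28, camera adjusted p = 0.00795, adjusted p = 0.367 with an estimated correlation). Iyd, which recovers iodide from iodotyrosines, rose and Slc16a10 fell (log2FC 0.35 and -0.45, SE 0.10 and 0.11, edgeR adjusted p = 0.0313 and 0.0183). Slc5a5, Tshr and Tg stood at log2FC -0.74, 0.55 and 0.53, edgeR adjusted p = 0.149, 0.073 and 0.0703. Iyd and Slc16a10 lost calls with the muscle covariate, at log2FC 0.21 and -0.28, SE 0.12 and 0.13 (adjusted p = 0.312 and 0.222). Iyd lost the call with limma (adjusted p = 0.191), without Empty replicate 1 (0.0618), 2 (0.102), TSH replicate 2 (0.082) and 3 (0.0523). Iyd and Slc16a10 lost calls without TSH replicate 1 (adjusted p = 0.103 and 0.0773). Slc16a10 lost the call with only the compared groups fitted (adjusted p = 0.0503) and without Empty replicate 3 (0.055).

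Of the mitosis genes 23 of 30 rose, or 29 adjusted over the list alone (median log2FC 1.62, camera adjusted p = 1.77e-27, adjusted p = 0.0366 with an estimated correlation). Mki67, the proliferation marker, and Prc1, a spindle midzone protein, stood higher (log2FC 2.08 and 1.94, SE 0.23 and 0.21, edgeR adjusted p = 0.000118 and 0.000118). Of the macrophage markers 14 of 16 rose, or 14 adjusted over the list alone (median log2FC 1.07, camera adjusted p = 3.35e-23, adjusted p = 0.0171 with an estimated correlation). Csf1r and Cx3cr1 stood at log2FC 1.25 and 1.39, SE 0.09 and 0.13, edgeR adjusted p = 1.53e-05 and 4.42e-05. In the MHC class II and antigen presentation list 9 of 13 rose, or 9 adjusted over the list alone (median log2FC 0.72, camera adjusted p = 1.42e-08, adjusted p = 0.0115 with an estimated correlation). H2-Aa and the dendritic cell integrin gene Itgax stood at log2FC 0.80 and 1.10, SE 0.11 and 0.16, edgeR adjusted p = 0.000516 and 0.000736. Of the interferon response genes 19 of 25 rose, or 22 adjusted over the list alone (median log2FC 0.90, camera adjusted p = 1.12e-20, adjusted p = 0.0173 with an estimated correlation). Oas1a, an antiviral enzyme, and Cxcl10, a chemokine, stood at log2FC 1.66 and 1.82, SE 0.18 and 0.21, edgeR adjusted p = 9.18e-05 and 0.000144.

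In the matrix list 13 of 21 rose and 1 fell, or 14 and 2 adjusted over the list alone (median log2FC 0.70, camera adjusted p = 3.67e-15, adjusted p = 0.0115 with an estimated correlation). Mfap5 and Lox stood at log2FC 1.41 and 1.68, SE 0.11 and 0.12, edgeR adjusted p = 1.53e-05 and 1.53e-05. Of the endothelial markers 13 of 16 rose, or 15 adjusted over the list alone (median log2FC 0.61, camera adjusted p = 3.05e-14, adjusted p = 0.0173 with an estimated correlation). Eng and Robo4 stood at log2FC 0.83 and 0.93, SE 0.09 and 0.11, edgeR adjusted p = 8.02e-05 and 0.000216. Among the C cell markers 11 of 13 fell, or 11 adjusted over the list alone (median log2FC -1.07, camera adjusted p = 1.41e-17, adjusted p = 0.0115 with an estimated correlation). The granule protein gene Scg2 and Pcsk2 stood at log2FC -1.28 and -1.16, SE 0.12 and 0.12, edgeR adjusted p = 4.57e-05 and 8.02e-05. The parathyroid markers had a median log2FC of -1.05 (camera adjusted p = 0.435).

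Of the oxidative phosphorylation genes 19 of 28 fell, or 25 adjusted over the list alone (median log2FC -0.43, camera adjusted p = 2.04e-09, adjusted p = 0.421 with an estimated correlation). The subunit genes Ndufs1 and Atp5c1 stood at log2FC -0.44 and -0.50, SE 0.10 and 0.12, edgeR adjusted p = 0.00962 and 0.0114. Of the white adipocyte markers 4 of 11 fell, or 7 adjusted over the list alone (median log2FC -0.74, camera adjusted p = 4.41e-07, adjusted p = 0.303 with an estimated correlation). Car3 and Lpl stood at log2FC -1.98 and -0.86, SE 0.25 and 0.13, edgeR adjusted p = 0.00055 and 0.000751. Mitochondrially encoded transcripts took 9.44% ± 0.838 of counts in Empty and 7.55% ± 0.766 in TSH (mean ± SD, n = 3), and more in each Empty library. Beside both lists stood the skeletal muscle markers, of which 1 of 19 fell, or 0 adjusted over the list alone (median log2FC -3.06, camera adjusted p = 2.01e-05, adjusted p = 0.561 with an estimated correlation). The lowest genes of the rule were Myl3 and Myh8, which are expressed in muscle (log2FC -11.32 and -7.60, SE 3.15 and 2.11, edgeR adjusted p = 0.0483 and 0.0482), and the highest were Slc34a2 and Car15, a carbonic anhydrase (log2FC 4.16 and 3.39, SE 0.42 and 0.80, edgeR adjusted p = 0.000219 and 0.0251). With edgeR there were 673 higher and 224 lower with the muscle covariate and 907 higher and 412 lower without TSH replicate 3, and limma called 823 higher and 1474 lower. Atp5c1, Car15, Myh8, Myl3 and Ndufs1 lost calls with the muscle covariate, at log2FC -0.48, 2.76, -3.88, -4.44 and -0.43, SE 0.16, 0.88, 3.42, 12.12 and 0.13 (adjusted p = 0.0942, 0.119, 0.555, 0.874 and 0.0777). Atp5c1, Myh8 and Myl3 lost calls with only the compared groups fitted (adjusted p = 0.0513, 0.158 and 0.178) and without TSH replicate 3 (0.0603, 0.156 and 0.191). Car15, Myh8 and Myl3 lost calls without Empty replicate 1 (adjusted p = 0.0973, 0.168 and 0.109), TSH replicate 1 (0.066, 0.123 and 0.131) and 2 (0.0666, 0.119 and 0.138). Car15 lost the call without Empty replicate 2 (adjusted p = 0.076) and 3 (0.0589). Myh8 and Myl3 lost calls with no filter (adjusted p = 0.0691 and 0.0694), with the replicate block (0.157 and 0.105) and with limma (0.0857 and 0.18). The log2FC was -3.67 and -5.43 for Myh8 and Myl3 without Empty replicate 1, -8.24 and -10.71 for Myh8 and Myl3 without TSH replicate 2 and -15.80 for Myl3 without TSH replicate 3.

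Methimazole without the TSH vector was given for 4 weeks, and edgeR called 99 higher and 186 lower. Of the mitosis genes 12 of 30 rose, or 28 adjusted over the list alone (median log2FC 1.23, camera adjusted p = 1.72e-36, adjusted p = 0.108 with an estimated correlation). Prc1, Mki67 and Cenpf, a kinetochore protein, rose (log2FC 1.54, 1.56 and 2.02, SE 0.21, 0.22 and 0.31, edgeR adjusted p = 0.00704, 0.00782 and 0.0104), Mki67 to 10.5 ± 2.31 against 3.57 ± 0.839 normalised CPM (mean ± SD, n = 3). The muscle marker score was lower in each Empty-MMI library than in each Empty library. With that score as a covariate edgeR called 0 genes, while without it 2614 genes had an unadjusted p under 0.05 and DESeq2 called 383 higher and 427 lower. Cenpf, Mki67 and Prc1 lost calls with the muscle covariate, at log2FC 2.28, 1.61 and 1.55, SE 0.42, 0.32 and 0.30 (adjusted p = 0.188, 0.218 and 0.218). Cenpf and Mki67 lost calls with limma (adjusted p = 0.134 and 0.0577).

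Of the matrix markers 6 of 21 rose, or 12 higher and 1 lower adjusted over the list alone (median log2FC 0.36, camera adjusted p = 2.27e-08, adjusted p = 0.108 with an estimated correlation). Col5a1 and Mfap5 stood at log2FC 0.59 and 0.58, SE 0.10 and 0.11, edgeR adjusted p = 0.0171 and 0.0238. In the thyroid hormone synthesis list edgeR called 0 of 17, against 6 at an unadjusted p under 0.05, 2 by DESeq2, 0 by limma, and 4 higher and 1 lower adjusted over the list alone (median log2FC 0.18, camera adjusted p = 0.015, adjusted p = 0.667 with an estimated correlation). Slc26a4, Slc5a5, Tshr and Tg stood at log2FC 0.63, 0.21, 0.71 and 0.17, edgeR adjusted p = 0.523, 0.825, 0.0859 and 0.745. Klf11, a transcription factor, rose (log2FC 1.47, SE 0.19, edgeR adjusted p = 0.00588), and Usp13 and the muscle gene Tpm2 fell (log2FC -5.58 and -4.56, SE 1.04 and 0.85, edgeR adjusted p = 0.0426 and 0.0444). For the skeletal muscle markers edgeR called 0 of 19, against 19 at an unadjusted p under 0.05, 13 by DESeq2, 5 by limma, and 19 lower adjusted over the list alone (median log2FC -5.28, camera adjusted p = 2.19e-14, adjusted p = 0.615 with an estimated correlation). By edgeR there were 34 higher and 83 lower without Empty replicate 1, 7 higher and 13 lower without Empty-MMI replicate 1, 63 higher and 52 lower without replicate 2 and 12 higher and 17 lower without replicate 3 of that group, and 38 higher and 63 lower with the replicate block, and limma called 21 higher and 237 lower. Col5a1, Klf11, Mfap5, Tpm2 and Usp13 lost calls with the muscle covariate, at log2FC 0.57, 1.64, 0.42, -2.93 and -2.70, SE 0.15, 0.27, 0.14, 0.68 and 0.88 (adjusted p = 0.378, 0.126, 0.489, 0.411 and 0.489). Col5a1 and Mfap5 lost calls with limma (adjusted p = 0.12 and 0.0555). Col5a1, Mfap5, Tpm2 and Usp13 lost calls with only the compared groups fitted (adjusted p = 0.0645, 0.11, 0.161 and 0.136), without Empty-MMI replicate 1 (0.0849, 0.0849, 0.172 and 0.166) and 3 (0.0624, 0.0889, 0.149 and 0.15). Tpm2 and Usp13 lost calls with no filter (adjusted p = 0.0607 and 0.061), with the replicate block (0.117 and 0.116), without Empty replicate 1 (0.0957 and 0.0952), 3 (0.0688 for each) and Empty-MMI replicate 2 (0.0931 and 0.0919). The log2FC was -3.76 and -4.81 for Tpm2 and Usp13 without Empty replicate 1 and -6.34 for Usp13 without Empty-MMI replicate 2.

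At 4 weeks, methimazole on top of TSH left 3 called genes in edgeR. Cxcl10 fell (log2FC -1.51, SE 0.20, edgeR adjusted p = 0.0308), and LOC115488503 and Lrrc26, chosen after their values were seen, rose (log2FC 1.44, SE 0.18, edgeR adjusted p = 0.0308 and log2FC 1.18, SE 0.17, edgeR adjusted p = 0.0362). Slc26a4, Slc5a5, Tshr and Tg stood at log2FC -0.13, 0.70, 0.01 and -0.65, edgeR adjusted p = 0.954, 0.6, 0.993 and 0.372. Of all genes 1438 had an unadjusted p under 0.05, DESeq2 called 39 higher and 43 lower and limma 7 higher and 2 lower. In the thyroid hormone synthesis list edgeR called 0 of 17, against 5 at an unadjusted p under 0.05, 1 by DESeq2, 0 by limma, and 1 higher and 1 lower adjusted over the list alone (median log2FC 0.02, camera adjusted p = 0.448, adjusted p = 0.816 with an estimated correlation). For the cholesterol biosynthesis genes edgeR called 0 of 24, against 10 at an unadjusted p under 0.05, 0 by DESeq2, 0 by limma, and 5 higher adjusted over the list alone (median log2FC 0.28, camera adjusted p = 2.95e-09, adjusted p = 0.816 with an estimated correlation). Hmgcs1 stood at log2FC 0.37, edgeR adjusted p = 0.364. Among the interferon response genes 1 of 25 fell, or 1 adjusted over the list alone (median log2FC -0.21, camera adjusted p = 0.000398, adjusted p = 0.816 with an estimated correlation). The skeletal muscle markers had a median log2FC of -2.00 (camera adjusted p = 0.00191, adjusted p = 0.816 with an estimated correlation). By edgeR 0 genes passed with the muscle covariate, with only the compared groups fitted and without TSH replicate 1, 2 or 3 or TSH-MMI replicate 1, 1 without TSH-MMI replicate 2, and 31 higher and 12 lower without TSH-MMI replicate 3. Cxcl10, LOC115488503 and Lrrc26 lost calls with the muscle covariate, at log2FC -1.50, 1.44 and 1.20, SE 0.22, 0.20 and 0.18 (adjusted p = 0.0916 for each). Cxcl10, LOC115488503 and Lrrc26 lost calls with only the compared groups fitted (adjusted p = 0.0793 for each), without TSH replicate 1 (0.0734, 0.107 and 0.217), 2 (0.175 for each) and 3 (0.137, 0.137 and 0.173). Cxcl10, LOC115488503 and Lrrc26 lost calls without TSH-MMI replicate 1 (adjusted p = 0.141 for each). Cxcl10 and Lrrc26 lost calls without TSH-MMI replicate 2 (adjusted p = 0.0909 and 0.0973). Lrrc26 lost the call with the replicate block (adjusted p = 0.0623).

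The combined treatment at 4 weeks raised Slc26a4 9.06-fold over Empty (log2FC 3.18, SE 0.38, edgeR adjusted p = 0.000167) and Dio2 2.69-fold (log2FC 1.43, SE 0.27, edgeR adjusted p = 0.00396). Of the thyroid hormone synthesis genes 10 of 17 rose, or 10 higher and 2 lower adjusted over the list alone (median log2FC 0.42, camera adjusted p = 0.00114, adjusted p = 0.238 with an estimated correlation). Ano1, Slc26a7, Duox1 and Dio1 rose (log2FC 0.58, 0.53, 1.34 and 0.42, SE 0.11, 0.12, 0.31 and 0.10, edgeR adjusted p = 0.00376, 0.00892, 0.0116 and 0.0141), while Slc5a5, Tshr and Tg stood at log2FC -0.04, 0.56 and -0.12, edgeR adjusted p = 0.961, 0.0686 and 0.729. In edgeR 1522 higher and 1036 lower passed. Ano1, Dio1, Dio2, Duox1 and Slc26a7 lost calls with the muscle covariate, at log2FC 0.61, 0.41, 1.20, 0.91 and 0.56, SE 0.17, 0.16, 0.39, 0.47 and 0.18 (adjusted p = 0.0829, 0.232, 0.146, 0.362 and 0.146). Dio1 and Duox1 lost calls without TSH-MMI replicate 1 (adjusted p = 0.0711 and 0.0519). Dio1 lost the call without TSH-MMI replicate 2 (adjusted p = 0.0516).

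Of the mitosis genes 27 of 30 rose, or 30 adjusted over the list alone (median log2FC 1.98, camera adjusted p = 1.35e-35, adjusted p = 0.0275 with an estimated correlation). Prc1 and Mki67 stood higher (log2FC 2.16 and 2.07, SE 0.21 and 0.23, edgeR adjusted p = 5.34e-05 and 9.68e-05). In the matrix list 14 of 21 rose, or 14 higher and 1 lower adjusted over the list alone (median log2FC 0.70, camera adjusted p = 1.3e-17, adjusted p = 0.0197 with an estimated correlation). Lox and Mfap5 stood higher (log2FC 1.72 and 1.43, SE 0.12 and 0.11, edgeR adjusted p = 1.12e-05 and 1.4e-05). Of the macrophage markers 14 of 16 rose, or 14 adjusted over the list alone (median log2FC 0.96, camera adjusted p = 7.69e-20, adjusted p = 0.0275 with an estimated correlation). Csf1r and Cx3cr1 stood higher (log2FC 1.04 and 1.20, SE 0.09 and 0.13, edgeR adjusted p = 3.05e-05 and 9.38e-05). Of the interferon response genes 14 of 25 rose, or 18 adjusted over the list alone (median log2FC 0.72, camera adjusted p = 4.54e-12, adjusted p = 0.0695 with an estimated correlation). Oas1a and Gbp3 stood at log2FC 1.68 and 1.00, SE 0.18 and 0.14, edgeR adjusted p = 7.93e-05 and 0.000412. Among the C cell markers 10 of 13 fell, or 1 higher and 11 lower adjusted over the list alone (median log2FC -0.99, camera adjusted p = 3.98e-13, adjusted p = 0.0197 with an estimated correlation). Pcsk2 and Scg3 stood at log2FC -1.11 and -1.25, SE 0.12 and 0.15, edgeR adjusted p = 8.88e-05 and 0.000152. The highest genes were Slc34a2 and Car15 (log2FC 4.45 and 4.28, SE 0.42 and 0.82, edgeR adjusted p = 0.000152 and 0.00939), and the lowest with counts in both groups were the muscle genes Sln and Myh8 (log2FC -9.18 and -8.43, SE 2.58 and 2.22, edgeR adjusted p = 0.049 and 0.0384). The skeletal muscle markers had a median log2FC of -5.01 (camera adjusted p = 3.14e-08, adjusted p = 0.328 with an estimated correlation). With edgeR there were 282 higher and 82 lower with the muscle covariate and 952 higher and 463 lower without TSH-MMI replicate 1, and limma called 1519 higher and 751 lower. Car15, Myh8 and Sln lost calls with the muscle covariate, at log2FC 3.43, -2.75 and -0.55, SE 1.00, 4.79 and 14.99 (adjusted p = 0.146, 0.837 and 0.994). Myh8 and Sln lost calls with no filter (adjusted p = 0.0547 and 0.0705), with the replicate block (0.137 and 0.111), with limma (0.0841 and 0.179), with only the compared groups fitted (0.159 and 0.202), without Empty replicate 1 (0.101 and 0.0637) and TSH-MMI replicate 1 (0.134 and 0.161). Myh8 and Sln lost calls without TSH-MMI replicate 2 (adjusted p = 0.117 and 0.132) and 3 (0.0672 and 0.157). The log2FC was -4.51 and -4.77 for Myh8 and Sln without Empty replicate 1 and -10.93 and -13.31 for Myh8 and Sln without TSH-MMI replicate 3.

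With methimazole in both groups, whose muscle scores overlapped, edgeR called 526 higher and 210 lower for TSH. Slc26a4 rose 5.85-fold (log2FC 2.55, SE 0.36, edgeR adjusted p = 0.0021), Dio2 2.75-fold (log2FC 1.46, SE 0.27, edgeR adjusted p = 0.0109) and Ano1 1.51-fold (log2FC 0.59, SE 0.11, edgeR adjusted p = 0.0105), while Slc5a5, Tshr and Tg stood at log2FC -0.24, -0.15 and -0.28, edgeR adjusted p = 0.762, 0.743 and 0.466. Of the macrophage markers 14 of 16 rose, or 15 adjusted over the list alone (median log2FC 0.87, camera adjusted p = 3.49e-25, adjusted p = 0.0206 with an estimated correlation). Csf1r and C1qb stood at log2FC 0.88 and 0.88, SE 0.09 and 0.12, edgeR adjusted p = 0.000478 and 0.00161. Of the interferon response genes 11 of 25 rose, or 19 adjusted over the list alone (median log2FC 0.70, camera adjusted p = 4.58e-19, adjusted p = 0.0217 with an estimated correlation). Gbp3 and Ifi44 stood at log2FC 0.97 and 1.14, SE 0.14 and 0.17, edgeR adjusted p = 0.0021 and 0.00266. In the antigen presentation list 8 of 13 rose, or 8 adjusted over the list alone (median log2FC 0.55, camera adjusted p = 1e-08, adjusted p = 0.0206 with an estimated correlation). H2-Aa and H2-Eb1 stood at log2FC 0.64 and 0.65, SE 0.11 and 0.11, edgeR adjusted p = 0.00621 and 0.00653. Ano1 and Dio2 lost calls without Empty-MMI replicate 1 (adjusted p = 0.0522 and 0.0538).

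In the matrix list 8 of 21 rose, or 11 adjusted over the list alone (median log2FC 0.40, camera adjusted p = 8.9e-10, adjusted p = 0.0217 with an estimated correlation). Lox and Mfap5 stood at log2FC 1.24 and 0.85, SE 0.12 and 0.11, edgeR adjusted p = 0.000244 and 0.00101. Of the endothelial markers 10 of 16 rose, or 13 adjusted over the list alone (median log2FC 0.39, camera adjusted p = 9.83e-13, adjusted p = 0.0217 with an estimated correlation). Plvap and Sox17 stood at log2FC 0.63 and 1.23, SE 0.09 and 0.18, edgeR adjusted p = 0.0021 and 0.00252. Among the C cell markers 8 of 13 fell, or 10 adjusted over the list alone (median log2FC -0.77, camera adjusted p = 1.14e-16, adjusted p = 0.0177 with an estimated correlation). Pcsk2 and Pcsk1 stood at log2FC -0.90 and -0.93, SE 0.12 and 0.14, edgeR adjusted p = 0.00145 and 0.00255. For the mitosis genes edgeR called 0 of 30, against 15 at an unadjusted p under 0.05, 4 by DESeq2, 2 by limma, and 9 higher adjusted over the list alone (median log2FC 0.57, camera adjusted p = 4.18e-08, adjusted p = 0.368 with an estimated correlation). Anln stood at log2FC 0.86, SE 0.24, edgeR adjusted p = 0.0622. The parathyroid markers had a median log2FC of -1.26 (camera adjusted p = 0.264) and the muscle markers a median log2FC of 0.21 (camera adjusted p = 0.618). Agr2 and Hlf were the lowest (log2FC -1.82 and -1.45, SE 0.17 and 0.23, edgeR adjusted p = 0.000244 and 0.00443), and Slc34a2 and Areg, an EGF receptor ligand, the highest (log2FC 3.04 and 2.59, SE 0.39 and 0.60, edgeR adjusted p = 0.00274 and 0.0462). In edgeR there were 259 higher and 88 lower without Empty-MMI replicate 1, 235 higher and 72 lower without Empty-MMI replicate 2 and 199 higher and 56 lower without TSH-MMI replicate 1, DESeq2 called 815 higher and 405 lower, and limma 761 higher and 111 lower. Areg lost the call with the muscle covariate, at log2FC 2.48, SE 0.58 (adjusted p = 0.0551). Areg lost the call with no filter (adjusted p = 0.0797), with the replicate block (0.0773), without Empty-MMI replicate 1 (0.161), 2 (0.173), 3 (0.0789) and TSH-MMI replicate 1 (0.152). Areg lost the call without TSH-MMI replicate 2 (adjusted p = 0.113) and 3 (0.0505).

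Whether the methimazole effect differed with and without TSH was tested as a difference of effects. By edgeR 0 genes passed, with 1754 at an unadjusted p under 0.05, DESeq2 called 69 higher and 102 lower, and limma called 2 (Ppp1r3c and Igkv15-103, named after their values were seen), where the median of all genes moved by 0.134 on the log2 scale. In simulated data for this difference edgeR recovered 8.96%, 52.2% and 90.9% of genes changed 1.5-, 2- and 4-fold, and 13% of DESeq2's calls were false. Slc26a4, Slc5a5, Tshr and Tg stood at log2FC -0.76, 0.50, -0.70 and -0.81, edgeR adjusted p = 0.633, 0.728, 0.423 and 0.362. For the mitosis genes edgeR called 0 of 30, against 17 at an unadjusted p under 0.05, 3 by DESeq2, 0 by limma, and 10 lower adjusted over the list alone (median log2FC -0.89, camera adjusted p = 2.23e-17, adjusted p = 0.408 with an estimated correlation). Mki67 stood at log2FC -1.57, edgeR adjusted p = 0.186. The skeletal muscle markers had a median log2FC of 3.45 (camera adjusted p = 1.93e-06, adjusted p = 0.715 with an estimated correlation). With edgeR 10 genes passed without Empty replicate 2 and 1 (Sash1, likewise) without Empty-MMI replicate 3.

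The TSH effect was also compared between the times, and edgeR called 74 higher and 165 lower at 4 weeks than at 1 week. Matrix markers had lower effects in 8 of 21 (12 adjusted over the list alone, median log2FC -0.52, camera adjusted p = 1.67e-15, adjusted p = 0.00362 with an estimated correlation). Col1a2 and Col1a1 stood at log2FC -1.09 and -1.10, SE 0.14 and 0.15, edgeR adjusted p = 0.00169 and 0.00169. Cartilage markers had lower effects in 1 of 10 (5 adjusted over the list alone, median log2FC -0.92, camera adjusted p = 0.000174, adjusted p = 0.0467 with an estimated correlation). Col11a2 stood at log2FC -2.21, SE 0.55, edgeR adjusted p = 0.0494. Mitosis genes had lower effects in 7 of 30 (14 adjusted over the list alone, median log2FC -1.32, camera adjusted p = 1.63e-18, adjusted p = 0.339 with an estimated correlation). Aurka, a mitotic kinase, and Kif20a stood at log2FC -1.63 and -1.50, SE 0.31 and 0.31, edgeR adjusted p = 0.0145 and 0.0233. Antigen presentation genes had higher effects in 3 of 13 (4 adjusted over the list alone, median log2FC 0.63, camera adjusted p = 4.04e-05, adjusted p = 0.262 with an estimated correlation). H2-Eb1 and H2-Aa stood at log2FC 0.70 and 0.69, SE 0.15 and 0.15, edgeR adjusted p = 0.0264 and 0.0282. The difference for Slc5a5 was log2FC -1.61, SE 0.37, edgeR adjusted p = 0.0439, while Slc26a4, Tshr and Tg stood at log2FC -0.76, -0.77 and 0.79, edgeR adjusted p = 0.486, 0.108 and 0.0863. Ptgds and Mex3a were the highest (log2FC 2.11 and 1.55, SE 0.30 and 0.25, edgeR adjusted p = 0.00223 and 0.00565), and Cacng1, a calcium channel subunit of muscle, and Adm2 the lowest (log2FC -4.67 and -2.26, SE 0.93 and 0.42, edgeR adjusted p = 0.0264 and 0.0184). The skeletal muscle markers had a median log2FC of -4.22 (camera adjusted p = 4.17e-08, adjusted p = 0.5 with an estimated correlation). Cacng1, Col11a2, H2-Aa, H2-Eb1, Kif20a and Slc5a5 lost calls with the muscle covariate, at log2FC -4.03, -2.60, 0.74, 0.69, -1.40 and -1.66, SE 1.13, 0.61, 0.18, 0.18, 0.35 and 0.43 (adjusted p = 0.123, 0.0553, 0.0595, 0.0787, 0.076 and 0.0983). Cacng1, Col11a2, H2-Aa and Slc5a5 lost calls without the libraries with thymocyte transcripts, at log2FC -4.58, -2.02, 0.61 and -1.48, SE 1.10, 0.55, 0.16 and 0.41 (adjusted p = 0.0625, 0.0738, 0.0589 and 0.0892). Adm2, Cacng1, Col11a2, H2-Eb1, Kif20a and Slc5a5 lost calls without TSH 1 week replicate 3 (adjusted p = 0.0582, 0.0717, 0.0904, 0.0582, 0.0582 and 0.11). Adm2, Cacng1, Col11a2, H2-Aa, H2-Eb1, Kif20a and Slc5a5 lost calls without TSH 4 week replicate 2 (adjusted p = 0.0501, 0.068, 0.105, 0.0608, 0.0534, 0.0534 and 0.0576). Cacng1 and Col11a2 lost calls with the replicate block (adjusted p = 0.0617 and 0.081). Cacng1, Kif20a and Slc5a5 lost calls without Empty 1 week replicate 1 (adjusted p = 0.067, 0.0592 and 0.0761). Cacng1, Col11a2, Kif20a and Slc5a5 lost calls without Empty 1 week replicate 2 (adjusted p = 0.0538, 0.117, 0.0574 and 0.0795). Cacng1, Col11a2, H2-Aa, H2-Eb1, Kif20a and Slc5a5 lost calls without TSH 4 week replicate 1 (adjusted p = 0.0693, 0.113, 0.0801, 0.0729, 0.0623 and 0.097). Cacng1, Col11a2 and Slc5a5 lost calls without TSH 4 week replicate 3 (adjusted p = 0.0548, 0.0571 and 0.0714). Col11a2 lost the call with RLE size factors (adjusted p = 0.0511) and with Tg, mitochondrial and ribosomal RNA genes left out (0.0511). Col11a2 and Slc5a5 lost calls with no filter (adjusted p = 0.0576 and 0.0723), without Empty 1 week replicate 3 (0.0861 and 0.0747) and Empty 4 week replicate 2 (0.0632 and 0.0531). Col11a2, H2-Aa, H2-Eb1, Kif20a and Slc5a5 lost calls without TSH 1 week replicate 2 (adjusted p = 0.117, 0.0738, 0.0688, 0.0562 and 0.0989). Col11a2 and H2-Aa lost calls without Empty 4 week replicate 3 (adjusted p = 0.102 and 0.0506). H2-Aa and H2-Eb1 lost calls with limma (adjusted p = 0.078 and 0.0758). Kif20a lost the call without Empty 4 week replicate 1 (adjusted p = 0.059). The log2FC was -3.89 for Cacng1 without TSH 1 week replicate 3 and -3.27 for Cacng1 without Empty 4 week replicate 1.

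By edgeR there were 59 higher and 90 lower for this difference with the replicate block and 37 higher and 70 lower with the muscle covariate, DESeq2 called 273 higher and 423 lower and limma 56 higher and 696 lower. Leaving out 1 library gave, at 1 week, 115 and 123 calls without Empty replicate 1 and 2, 97 and 67 without TSH replicate 2 and 3, and at 4 weeks 84, 103 and 131 without TSH replicate 1, 2 and 3. Over the 16742 genes tested at both times, 962 were higher and 369 lower with TSH at both, against 218 and 90.6 for independent lists, and 12 were called in opposite directions. The log2 fold changes of 1 and 4 weeks had Pearson's r = 0.401 and Spearman's rho = 0.512 across genes, which are not independent replicates.

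For the methimazole effect under TSH, the difference between 4 weeks and 1 week gave 0 called genes in edgeR (792 at an unadjusted p under 0.05), 1 higher and 1 lower in DESeq2 (Cavin2 and Nsg2, named after their values were seen) and 0 in limma. Of the matrix markers edgeR called 0 of 21, against 9 at an unadjusted p under 0.05, 0 by DESeq2, 0 by limma, and 5 higher adjusted over the list alone (median log2FC 0.30, camera adjusted p = 2.27e-11, adjusted p = 0.0182 with an estimated correlation). Between the 4-week TSH effects without and with methimazole, 416 genes were higher and 138 lower in both, against 44.8 and 11.8 for independent lists, with 2 in opposite directions among 17355 (Tnip1 and Map3k13, named after their values were seen), r = 0.406 and rho = 0.472 across genes. Of 4094 genes called for TSH at 1 week 3 moved back with methimazole (Col15a1, Col6a1 and Tbc1d4). In 10 simulations of no change the mean was 0.2 and the most 1. At 4 weeks 2 of 2452 moved back (Cxcl10 and Lrrc26), against a mean of 0.1. The sign was opposite in 73.9% and 62.2%, above and below the simulated 60.7% to 63.1% and 63.9% to 65.9%, so the weeks disagree.

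**Figure D3:**
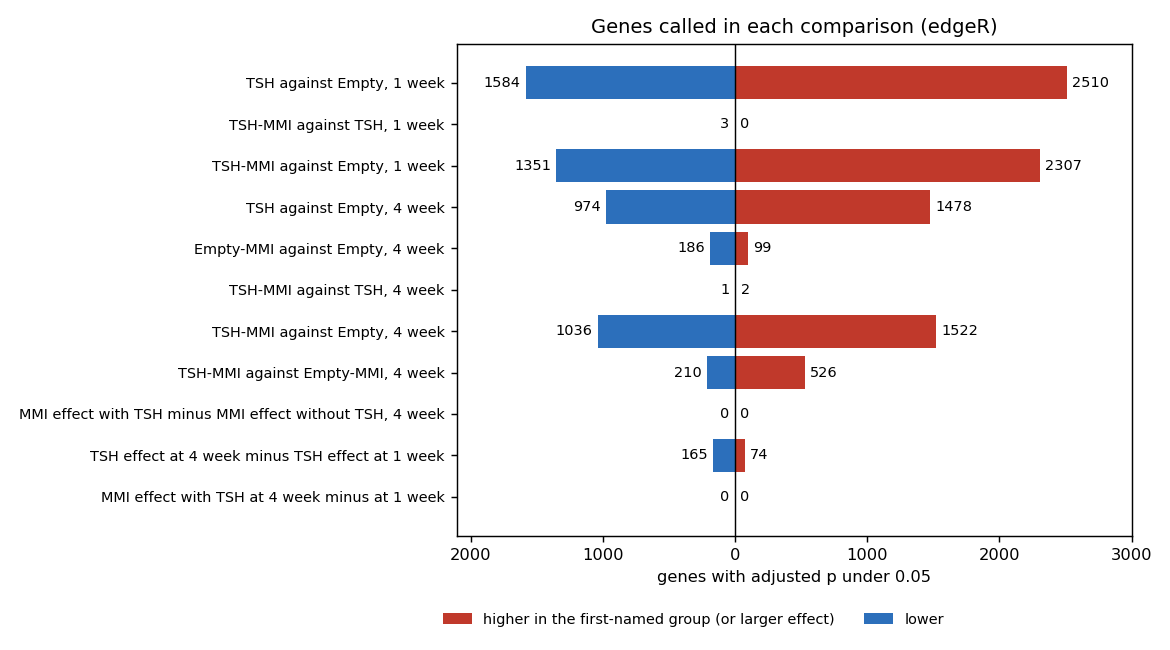
Number of genes with an edgeR adjusted p under 0.05 in each of the 11 comparisons, higher (right) and lower (left). The bars of TSH or TSH-MMI against Empty reach 1478 to 2510 genes higher, and those of methimazole on top of TSH at most 3 in total.

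**Figure D4:**
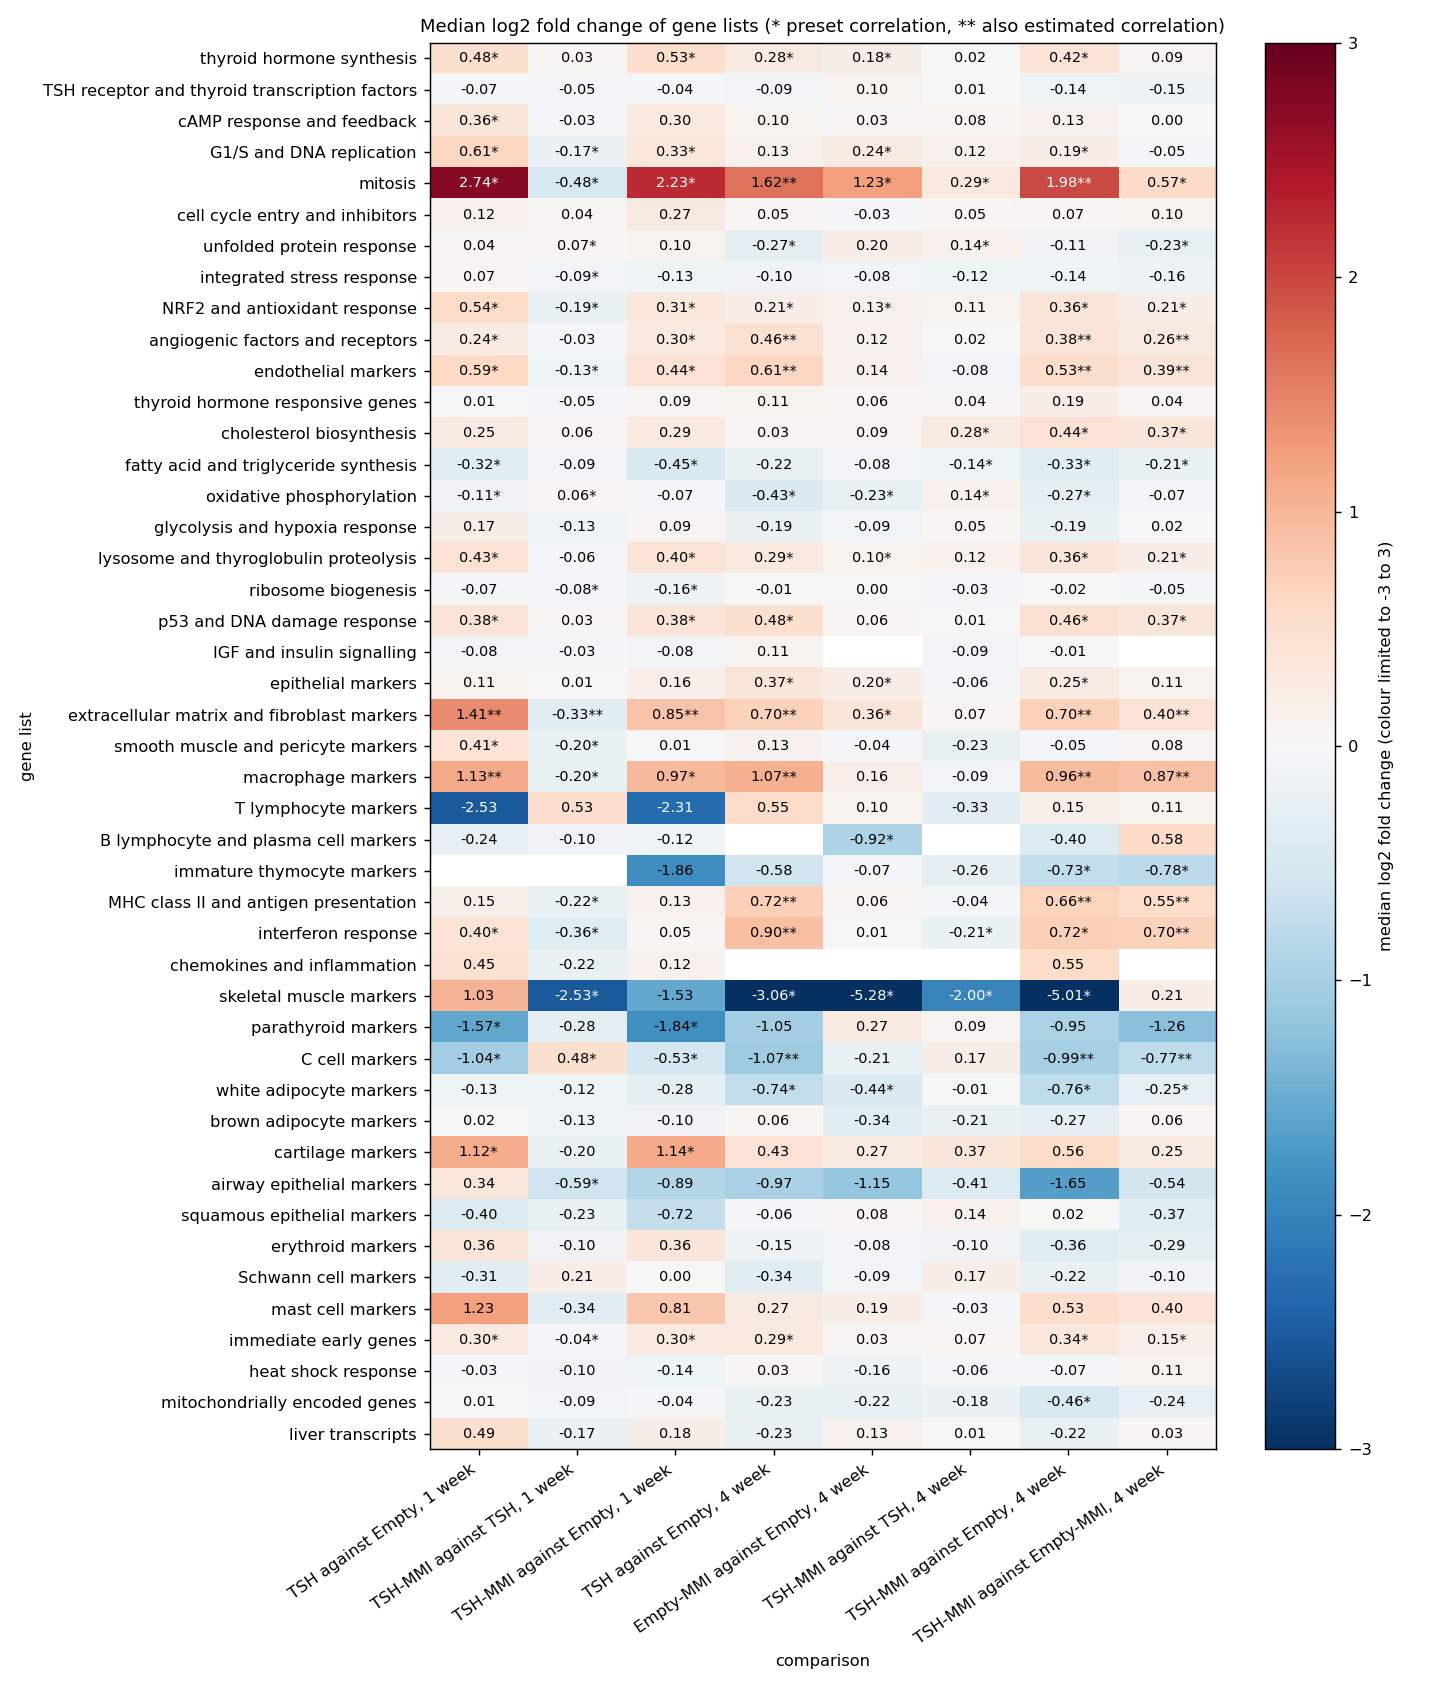
Median log2 fold change of the 45 tested gene lists (vertical) in the 8 pairwise comparisons (horizontal), with the value in each cell; 1 star marks an adjusted p under 0.05 with the preset correlation and a second star also with an estimated correlation, and cells without a value belong to lists with a member at 0 counts in a whole group. Matrix markers lie between 0.40 and 1.41 in the 5 comparisons of a TSH group with a group without TSH.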

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

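Tests by splits of libraries were planned before the data were examined, those of dilution were chosen after their results were seen, and the other tests in between, before theirs were seen. The TSH effect differed between 4 weeks and 1 week in 239 genes by edgeR, and in 20 of the 45 gene lists by camera with the preset correlation, of which 2 remained with an estimated correlation. For the methimazole effect with and without TSH 12 lists differed, and 0 with an estimated correlation (3 at an unadjusted p under 0.05). For the methimazole effect under TSH between the weeks 13 differed, and 1 with an estimated correlation. Between the weeks the TSH effect on matrix markers differed by a median log2FC of -0.52, on cartilage markers by -0.92, and the methimazole effect on matrix markers by 0.30. Single genes with a difference in the TSH effect were Cacng1 (-4.67), Adm2 (-2.26), Col11a2 (-2.21), Aurka (-1.63), Slc5a5 (-1.61), Kif20a (-1.50), Col1a1 (-1.10), Col1a2 (-1.09), H2-Aa (0.69), H2-Eb1 (0.70), Mex3a (1.55) and Ptgds (2.11), all as log2FC.

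Other splits of the same libraries were counted. For the 8 pairwise comparisons the 10 splits are too few for a share under 0.05. For TSH against Empty at 1 week the real split gave 4094 genes and 1 of 10 splits gave as many, with at most 0 in any other. TSH-MMI against TSH at 1 week had 3 genes, 2 of 10 splits with as many, and 9 in the highest other. In 5 comparisons 1 split was as large and the highest other gave 0: TSH-MMI against Empty at 1 week (3658 genes) and, at 4 weeks, TSH against Empty (2452), Empty-MMI against Empty (285), TSH-MMI against TSH (3) and TSH-MMI against Empty (2558). TSH-MMI against Empty-MMI gave 736, with 1 split as large and 1 in the highest other. For the difference of the TSH effect between the weeks, 5 of 30 splits gave at least 239 genes and the highest other gave 1988. The 4 others as large kept TSH and Empty of a single time point whole, so they hold its full TSH effect. Splits with no such pair gave at most 0 but mix TSH and Empty libraries, so neither kind decides about chance. For the methimazole effect with and without TSH and for that between the weeks, 30 of 30 splits gave at least the real 0, with 32 and 1 in the highest other.

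The genes lower in TSH than in Empty at 4 weeks may stem from skeletal muscle in the Empty libraries, whose muscle score was the week's highest. Over the 9 libraries of 1 week, the median within-group correlation of these 972 genes with the muscle score was -0.013. Of them 14.8% lay over 0.7, against 4.65% of all genes. The muscle covariate parts Empty from TSH and cannot decide (224 lower, 673 higher calls left). At 1 week scores were mostly lower, so muscle stays open. An effect of TSH also present at 1 week predicted lower values there, and 80.6% of the set had a negative log2FC. For the 185 genes lower in Empty-MMI the median correlation was 0.721, which fits muscle in Empty libraries. A methimazole effect on these genes stays untested.

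Of the 13 C cell markers 11 fell with TSH in each week and Ret rose at 1 week, where the list's call was lost with an estimated correlation (adjusted p = 0.194, against 0.0115 at 4 weeks). Parathyroid tissue may differ between libraries, but with its score as a covariate the median log2FC of the C cell markers was -1.16 at 1 week and -1.10 at 4 weeks, which argues against it. Dilution by cells that multiply would lower markers of other tissues alike, and the Schwann cell score changed by -0.25 and -0.46 (log2), 0.74 (SE 0.23) and 0.68 (SE 0.23) above the C cell score. At 1 and 4 weeks median log2FC were -0.13 and -0.74 for white and 0.02 and 0.06 for brown adipocyte markers. Parathyroid markers had -1.57 and -1.05. The tissues disagree, and the tests were chosen after their results were seen. Dilution, fewer C cells and lower transcript levels per cell stay open.

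Fewer genes were called for TSH at 4 weeks than at 1 week. A larger spread between the 4-week libraries with effects of one size could account for this, and so could a smaller effect. Over 731 genes called in TSH-MMI against Empty-MMI, the mean signed effect at 4 weeks was 0.876 of that at 1 week, which lies between the values that either would need, so they cannot be told apart. Over the 16742 genes tested in both weeks, the median SE at 4 weeks was 1.18 times that at 1 week.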

How the results depend on the processing

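The alternatives with the muscle covariate, without the libraries with thymocyte transcripts and without Tg, mitochondrial and ribosomal RNA genes were chosen after the data were seen, and the others before. The cause was not tested for any change given here. Over named genes, counted per comparison, 187 of 203 values kept their side of the threshold with DESeq2, 185 with limma on FPKM, 193 with no filter, 202 with RLE size factors, 189 with the replicate block and 163 with the muscle covariate. In the 39 calls lost with the muscle covariate, the log2FC was a median of 0.961 times and its SE 1.27 times that without it, and 11 log2FC were smaller by more than their SE. Of 1338 gene values with 1 library left out, 1172 kept it, 157 lost the call, 7 gained one and 2 with no call in either fit changed sign. Of 173 called gene list results 172 kept their call with RLE size factors, 173 with no filter, 171 with the replicate block and 29 with an estimated correlation.

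With DESeq2 the number of called genes became 148 for TSH-MMI against TSH at 1 week, 810 for Empty-MMI against Empty, 82 for TSH-MMI against TSH at 4 weeks and 1220 for TSH-MMI against Empty-MMI. For the differences it became 171 for methimazole with and without TSH, 696 for TSH between the weeks and 2 for methimazole under TSH between the weeks. It also gave 842 genes shared in direction between the TSH effects without and with methimazole, and 99 genes at 1 week and 34 at 4 weeks that methimazole moved back. With limma the count was 0 for TSH-MMI against TSH at 1 week, where 1462 genes had an unadjusted p under 0.05 in edgeR, 9 at 4 weeks, 2 for methimazole with and without TSH and 752 for TSH between the weeks. With no filter it was 5 for TSH-MMI against TSH at 1 week, with 14 lists called at 4 weeks. With only the compared groups fitted, 73 genes were called for Empty-MMI against Empty and 0 for TSH-MMI against TSH at 4 weeks. With the muscle covariate the counts were 0 for TSH-MMI against TSH in both weeks, 897 for TSH against Empty at 4 weeks, 0 for Empty-MMI against Empty, 364 for TSH-MMI against Empty at 4 weeks and 107 for TSH between the weeks. Without the libraries with thymocyte transcripts 0 genes were called for TSH-MMI against TSH at 1 week. Genes called with at least a 2-fold change numbered 1017 for TSH against Empty, 0 for TSH-MMI against TSH and 762 for TSH-MMI against Empty at 1 week, and at 4 weeks 731 for TSH, 166 for Empty-MMI and 860 for TSH-MMI against Empty, 203 for TSH-MMI against Empty-MMI and 96 for TSH between the weeks.

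Same-numbered samples across groups deviated with correlations of -0.246 to 0.267 at 1 week and -0.251 to 0.256 at 4 weeks. Other pairs gave -0.372 to 0.358 and -0.332 to 0.282, so pairing stays open. With the replicate block 0 genes were called for TSH-MMI against TSH at 1 week, 101 for Empty-MMI against Empty and 149 for TSH between the weeks. With an estimated correlation 2, 1 and 1 lists were called at 1 week for TSH against Empty, TSH-MMI against TSH and TSH-MMI against Empty, and at 4 weeks 8 for TSH against Empty, 0 for Empty-MMI against Empty, 0 for TSH-MMI against TSH, 7 for TSH-MMI against Empty and 7 for TSH-MMI against Empty-MMI. For the differences they were 0 for methimazole with and without TSH, 2 for TSH between the weeks and 1 for methimazole under TSH between the weeks.

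Leaving out 1 library gave 2649 to 4114 called genes for TSH against Empty, 0 to 4 for TSH-MMI against TSH and 2094 to 3489 for TSH-MMI against Empty at 1 week. At 4 weeks it gave 1319 to 2465 for TSH against Empty, 20 to 326 for Empty-MMI against Empty, 0 to 43 for TSH-MMI against TSH, 1415 to 2373 for TSH-MMI against Empty and 255 to 625 for TSH-MMI against Empty-MMI. For the differences it gave 0 to 10 for methimazole with and without TSH, 67 to 320 for TSH between the weeks and 0 to 0 for methimazole under TSH between the weeks. In simulated data for methimazole with and without TSH, edgeR recovered 8.96% of genes changed 1.5-fold, so most 1.5-fold differences were not detectable at this depth and number of libraries.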

Other observations

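In TSH against Empty at 4 weeks, these gene groups, fixed in advance, stood beside skeletal muscle markers with a median log2FC of -3.06. Of the lysosome and thyroglobulin proteolysis genes 9 of 24 rose and 1 fell, or 12 and 2 adjusted over the list alone (median log2FC 0.29, camera adjusted p = 0.00015, adjusted p = 0.398 with an estimated correlation). The cathepsin genes Ctsl and Ctss stood at log2FC 0.77 and 1.22, SE 0.10 and 0.15, edgeR adjusted p = 0.000228 and 0.00024. Of the antioxidant genes 11 of 25 rose and 3 fell, or 11 and 4 adjusted over the list alone (median log2FC 0.21, camera adjusted p = 0.000469, adjusted p = 0.421 with an estimated correlation). Txnrd1, a thioredoxin reductase, and Sod3, an extracellular superoxide dismutase, stood at log2FC 0.97 and 1.17, SE 0.12 and 0.15, edgeR adjusted p = 0.000199 and 0.000276. In the p53 and DNA damage list 8 of 20 rose and 1 fell, or 10 and 1 adjusted over the list alone (median log2FC 0.48, camera adjusted p = 0.000139, adjusted p = 0.303 with an estimated correlation). Gdf15 and the nuclease gene Aen stood at log2FC 2.48 and 0.56, SE 0.29 and 0.11, edgeR adjusted p = 0.000548 and 0.00483. Of the epithelial markers 6 of 16 rose, or 8 adjusted over the list alone (median log2FC 0.37, camera adjusted p = 0.000263, adjusted p = 0.332 with an estimated correlation). The keratin gene Krt19 and the claudin gene Cldn4 stood at log2FC 0.98 and 0.79, SE 0.17 and 0.16, edgeR adjusted p = 0.00199 and 0.00618. In the unfolded protein response list 4 of 24 fell, or 9 adjusted over the list alone (median log2FC -0.27, camera adjusted p = 0.000609, adjusted p = 0.627 with an estimated correlation). Sec61b, a translocon subunit, and Derl3 stood at log2FC -0.63 and -0.49, SE 0.10 and 0.13, edgeR adjusted p = 0.00101 and 0.0197. Among the thyroid hormone responsive genes 2 of 12 rose and 1 fell, or 2 and 1 adjusted over the list alone (median log2FC 0.11, camera adjusted p = 0.372, adjusted p = 0.627 with an estimated correlation). Hr, a corepressor, and Dio3, which inactivates thyroid hormone, stood at log2FC 0.84 and 2.98, SE 0.14 and 0.53, edgeR adjusted p = 0.00139 and 0.00242, and Rasd1, a small G protein, fell 1.99-fold (edgeR adjusted p = 0.00665). Cldn4, Derl3 and Rasd1 lost calls with the muscle covariate, at log2FC 0.69, -0.42 and -0.93, SE 0.21, 0.16 and 0.29 (adjusted p = 0.0759, 0.15 and 0.0774). Derl3 lost the call with only the compared groups fitted (adjusted p = 0.0579), without Empty replicate 2 (0.0517), 3 (0.0678), TSH replicate 1 (0.0864) and 3 (0.0516).

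The test of clock genes was chosen after the data were examined and before its result was seen. At 1 week the median log2FC of TSH against Empty was 0.2 over 10 clock output genes and -0.48 over 5 genes of the other arm. A shifted clock phase with lower output genes required the output arm to lie below the other, and it lay 0.69 above, so a shift of another kind may remain, untested.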
